A study of Rattus norvegicus with 6 samples.

How the data were processed

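Total RNA from femur and tibia marrow cells was sequenced as 6 libraries, 3 exercise and 3 control, per the labels' protocols. The submitters' processing notes name TopHat, TopHat2 and StringTie without roles or versions; the genome build, the annotation, the strand setting and the circRNA caller are not given in the sources used here. Coordinates are those of the deposited tables. Gene symbols are those of the tables, and RefSeq symbols (assembly GRCr8) were used only to class loci: 15761 of 24957 loci matched, 35 of them as long non-coding.

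The gene table holds FPKM values and estimated counts made by the authors for 24957 loci, of which 18691 carry IDs of an assembled transcript set and 607 join several gene names, per the file headers. The deposited counts are whole numbers derived from coverage: the ratio of count to FPKM was constant within a gene to 0.0122% (largest SD, genes over 5000 counts). Of 2805 low counts, 89.8% were 0 to 1 above the value computed from FPKM, as rounding up gives, 10.2% were over 1 above it, and 0.07% lay below it by more than a tolerance of 0.05 counts. Overlapping and near-identical genes can share reads in such estimates. The circRNA table holds deposited junction read counts for 38697 circRNAs, 32304 exonic, 4026 intronic and 2367 intergenic by the authors' type column, and a normalised signal (SRPBM) that equals the count times 1000000000 over 1 denominator per library. Each of the 6 denominators was a multiple of 150. SRPBM totals were 2.68 times as high after exercise on average, against 1.51 times for junction reads per 1000000 gene counts, and SRPBM was not used in tests.

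Before the data were examined, limma on log2(FPKM + 1) was planned for FPKM and edgeR for counts. As counts were present, edgeR 4.0.16 (R 4.3.3) was the main test, with limma 3.58.1 on FPKM and DESeq2 1.42.0 as alternatives. Genes with a mean FPKM of 1 or more over the 6 libraries were tested (14218) with TMM scaling, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size over the square root of F. The median log2 fold change of all genes was 0.02 with TMM and -0.12 with library sizes alone. circRNAs passing filterByExpr with a minimum count of 5 were tested in the same way (1403, holding 53.1% of junction reads). Floors of 3 counts cover counting error only, while the SE and SD values include the spread between libraries.

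Gene lists written before the data were examined were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry, where a list had 5 tested loci; 25 lists did. Members were matched by exact symbol. Lists of epidermis, adipocyte and growth plate cartilage genes, and second lists of muscle, epidermis, cartilage and platelet genes, were chosen after the data were examined. The genes named were the 10 of smallest unadjusted p in each direction with an official symbol and no overlap between groups, since none passed; up to 4 members of smallest p and the first member of each list; the named long non-coding RNA genes; the 5 unnamed loci of smallest p; and 5 circRNAs in each direction with the 5 most abundant. The text gives fewer members for lists that did not pass. Lyz2, S100a8, Thy1, Cxcl12, Adipoq, Krt10, Acta1, Col9a3 and Spp1 were chosen after their values were seen. So were circRNA9848, circRNA26002 and the locus LOC103690035.

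Samples with the same number deviated together: the correlations of deviations from group means were 0.36, 0.12 and 0.39 for numbers 1, 2 and 3, each above 0.1, and the highest with another number were 0.34, 0.08 and -0.31. By the threshold of 0.1 the numbers were taken as pairing the libraries for the replicate block and for grouping splits, from the data and not from the labels. The main fits did not use the pairing. For numbers 1 and 2 the margin over another number was small. Deviations within a group sum to 0, so likeness of control 3 and exercise 3 alone raises the correlations among the other libraries. The threshold therefore cannot decide whether numbers 1 and 2 are pairs. Exercise 1 and 2 both lay nearer control 2 (chi-square 49.2 and 52.1 per gene) than control 1 (63.5 and 61.8). Exercise 1 and 2 were the closest libraries, with a chi-square of 16.2 per gene and 2.90 per circRNA where sampling noise gives 1, and were counted as 2. The scripts were tested on simulated data. With the spread of the 6 libraries, the circRNA test recovered 0%, 6.78% and 20.7% of 2-fold, 4-fold and 8-fold changes among 1403 circRNAs. With the dispersion of each gene in control 1, control 2, exercise 1 and exercise 2, the gene test on 14218 genes recovered 21.4%, 84.4% and 92.4%, with 12 false calls. Alternatives covered filters, pseudocounts, scaling, the replicate block, other tools and leaving out each library.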

Results

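RNA was sequenced from bone marrow cells of Sprague-Dawley rats, an outbred laboratory strain, labelled as bone marrow mesenchymal stem cells (the stromal cells that can form bone, cartilage and fat) taken from femur and tibia. The 12 rats were 8 weeks old at the start and were divided at random into 6 that ran on a treadmill for 8 weeks and 6 controls. Running began at 10 m/min for 20 min and reached 20 m/min on a 5 degree slope for 60 min, on 5 days a week. The 6 libraries analysed comprise 3 of the exercise group and 3 of the control group. The labels do not say whether a library holds 1 rat or a pool, so p-values measure the spread between these libraries only. Estimated gene counts summed to 74775636, 86658478 and 79549613 in control 1, 2 and 3 and to 92939008, 93536894 and 92538795 in exercise 1, 2 and 3. Reads across circular RNA (circRNA) back-splice junctions numbered 48180, 39225 and 36827 in the controls and 87639, 98544 and 32887 in the exercise libraries.

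Every library held abundant transcripts of blood-forming marrow cells. Lyz2, the lysozyme of monocytes and neutrophils, was at 4006 ± 1366 FPKM in controls and 3136 ± 1044 after exercise (SD, n = 3 each). S100a8, a neutrophil calcium-binding protein, was at 3571 ± 626 and 2338 ± 1480 FPKM. Haemoglobin loci took 8.70% ± 2.18 of gene counts in controls and 9.29% ± 3.63 after exercise (SD, n = 3 each). Of the stromal marker list, whose members need not be limited to stroma, Cxcl12, a niche chemokine, and Thy1, a surface marker, were at 123 ± 26.6 and 11.6 ± 3.12 FPKM in controls. After exercise they were at 96.7 ± 6.83 and 10.6 ± 2.75 FPKM. Exercise 3 carried skeletal muscle transcripts, with Acta1, the skeletal actin, at 11791 FPKM against 82 to 2521 FPKM in the other libraries. Muscle loci were taken as those named Acta1, Myh, Ckm, Tnn, Mylpf, Mb or Actn, and the name Myh can take in myosins outside skeletal muscle. They took 5.72% of the gene counts of exercise 3, 1.53% of those of control 3, and 0.125% to 0.463% of those of the other 4 libraries. Control 3 carried fat and skin transcripts: the adipocyte hormone Adipoq was at 225 FPKM there and at 4.04 to 41.1 FPKM elsewhere, and the epidermal keratin Krt10 at 228 FPKM against 0.313 FPKM or less. The first principal component, with 48.9% of the variance, separated control 3 and exercise 3 from the other 4 libraries, and the third, with 12.4%, separated control 1 and 2 from exercise 1 and 2.

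**Figure D1:**
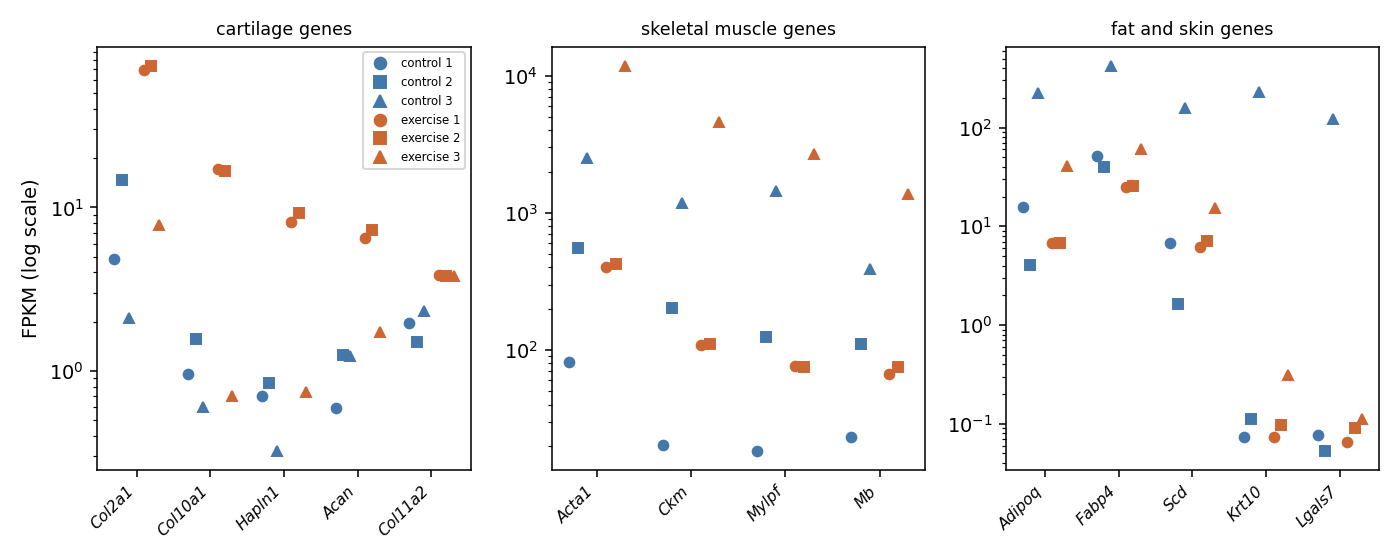
FPKM (log scale) of cartilage, skeletal muscle, and fat and skin genes in each of the 6 libraries, 1 point per library, blue for control and orange for exercise. Col2a1 stood at 69.4 and 73.5 FPKM in exercise 1 and 2, Acta1 at 11791 FPKM in exercise 3 and Krt10 at 228 FPKM in control 3.

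The first comparison asked which genes differed in marrow cells after treadmill training. Of 14218 genes tested, 0 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 398, and the smallest adjusted p was 0.535, at LOC103690035 on chromosome 5 (64566804 to 64584309), listed at 0 in all 3 exercise libraries and at least 287-fold lower against a floor of 3 counts per library. DESeq2, run on the same counts, called 18 genes, 7 higher and 11 lower after exercise. Leaving out both control 3 and exercise 3, an alternative chosen after seeing the data, gave 16 genes in edgeR, 8 higher and 8 lower. limma voom with sample weights, chosen likewise, gave 5 genes, all lower. LOC103690035 was called by DESeq2 (adjusted p = 1.73e-18) and by limma voom (adjusted p = 0.00721), but not in edgeR without control 3 and exercise 3. That edgeR fit set control 1 and 2 against exercise 1 and 2, the closest libraries (chi-square 16.2 per gene). Its p-values hold only if exercise 1 and 2 are independent. The exercise libraries lay wholly above the controls for 408 genes and wholly below for 794, together 8.45% of genes. Chance gives 10% if the 6 libraries are exchangeable, which the likeness of control 3 and exercise 3 puts in doubt. The other 3 splits that part all 3 pairs of the same number, compared after seeing the data, gave 2.85%, 4.08% and 10.3%. On counts simulated with the spread of these libraries, the same test recovered 0% of genes changed 2-fold or 4-fold and 10.8% of genes changed 8-fold.

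The genes named next did not pass in edgeR. They are those of smallest unadjusted p whose exercise libraries all lay on 1 side of all controls. Pitpna, a phosphatidylinositol transfer protein on chromosome 10 at 63731711 to 63775586, was at 11.8 ± 1.21 FPKM in controls and 4.46 ± 0.747 after exercise, a log2 fold change of -1.40 ± 0.17 (SE; unadjusted p = 1.65e-04, edgeR adjusted p = 0.861). Bri3 had a log2 fold change of -1.87 ± 0.29 and Clca5, of a chloride channel accessory family, one of -1.57 ± 0.27. Among genes with an official symbol, DESeq2 called these 3, and Gng11, Actr3b, Ltbp2, Col9a3 and Oma1. Gng11, a G protein gamma subunit (-0.90 ± 0.19), and Prkar2b, a regulatory subunit of protein kinase A (-0.72 ± 0.18), also lay below. So did Anapc10, a subunit of the anaphase-promoting complex (-0.95), the adaptor Nck1 (-1.13), the translation initiation factor Eif3m (-0.67), the serpin Serpinb2 (-1.56) and Mup4 (-2.06), whose gene family has near-identical copies. On the higher side stood Actr3b, related to the actin-nucleating Arp2/3 complex (1.69 ± 0.34), Ltbp2, a matrix protein of the fibrillin family (0.92 ± 0.19), and Col11a2, a cartilage collagen (1.02 ± 0.22). Arsb, a lysosomal sulfatase (0.73), Ubl7 (0.71), Lbp, which binds bacterial lipopolysaccharide (0.65), the mitochondrial protease Oma1 (0.70), Clec3a (1.39), the cartilage proteoglycan Acan (2.44) and the sterol regulator Srebf2 (0.67) completed that side.

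The library titles carry the tag lncRNA, read here as long non-coding RNA. Few loci carried names of such RNA: 5 tested loci carried a symbol of that class, and 0 of them had an unadjusted p under 0.05. Of the 23 long non-coding genes listed before the data were examined only Tug1 was found by name, at 6.41 ± 2.16 FPKM in controls and 3.86 ± 0.529 after exercise (log2 fold change -0.73 ± 0.31, unadjusted p = 0.0540, edgeR adjusted p = 0.992). Unnamed loci numbered 987, with 26 at an unadjusted p under 0.05 and 0 past adjustment in edgeR with all 6 libraries. The locus MSTRG.18753, on chromosome 9 at 121915525 to 121918921, was listed at 0 in all 3 exercise libraries and at 16.4, 12.5 and 5.00 FPKM in the controls, at least 1405-fold lower against a floor of 3 counts per library. Alternatives called MSTRG.18753: DESeq2 (adjusted p = 1.44e-22), edgeR without control 3 and exercise 3 (adjusted p = 0.0339) and limma voom with sample weights (adjusted p = 0.0148). MSTRG.5859 had a log2 fold change of 1.48 ± 0.38, MSTRG.7497 one of -2.82 ± 0.73, MSTRG.15331 one of -0.79 ± 0.21, and MSTRG.17649 was at 1.91 ± 0.394 FPKM in controls and 0.955 ± 0.131 after exercise. A 0 at an assembled locus can be a failed estimate.

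Cartilage genes formed the list that ranked highest after exercise. Of 11 tested chondrogenic loci 10 had a log2 fold change above 0, with a median of 2.44 (camera adjusted p = 9.99e-08 with a preset correlation, adjusted p = 0.270 with an estimated correlation). Col2a1, the main cartilage collagen, was at 69.4 and 73.5 FPKM in exercise 1 and 2, at 7.76 FPKM in exercise 3 and at 4.83, 14.8 and 2.10 FPKM in the controls. Col10a1, the collagen of hypertrophic cartilage, had a log2 fold change of 3.58 ± 1.21, the link protein Hapln1 one of 3.36 ± 1.03 and Acan one of 2.44 ± 0.67. Acan alone of these 4 lay above all controls in every exercise library, and the list's lead gene Sox9 was below the expression minimum. In the fit without control 3 and exercise 3, Hapln1 and Col9a3, a cartilage collagen outside the list, passed (edgeR adjusted p = 0.0215 for both). That fit counts exercise 1 and 2, the closest libraries (chi-square 16.2 per gene), as independent, which the labels do not settle. With all 6 libraries no member passed over all genes, nor when adjusted over the list alone, where the smallest adjusted p was 0.0921 in edgeR.

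Osteoclast genes also ranked higher, though only 5 of the 11 genes listed were tested. All 5 lay above 0, with a median log2 fold change of 0.83 (camera adjusted p = 6.85e-04, adjusted p = 0.270 with an estimated correlation). Acp5, the tartrate-resistant phosphatase of osteoclasts, was at 21.8, 25.7 and 17.7 FPKM in exercise 1, 2 and 3 and at 8.81, 9.56 and 18.0 FPKM in the controls. Mmp9, a matrix protease also made by neutrophils, had a log2 fold change of 0.83 ± 0.34, Atp6v0d2 one of 1.09 ± 0.74 and Nfatc1 one of 0.45 ± 0.29. The remaining tested locus, Itgb3 (0.30), also stands in the platelet list. Interferon response genes ranked higher with 17 of 20 loci above 0 and a median of 0.25 (camera adjusted p = 0.00156, adjusted p = 0.943 with an estimated correlation). Irf7, a transcription factor of that response, was at 101 and 113 FPKM in exercise 1 and 2 and at 32.1 FPKM in exercise 3, against 28.4, 30.2 and 57.4 FPKM in controls. It passed without control 3 and exercise 3 (edgeR adjusted p = 0.0339), with exercise 1 and 2 counted as independent, and not with all libraries. Stat2 had a log2 fold change of 0.39 ± 0.16, Oasl one of 0.74 ± 0.34 and Mx1 one of 0.37 ± 0.23. The interferon call ended without exercise 1 (adjusted p = 0.176) or exercise 2 (adjusted p = 0.0829) and with these summed (0.117), by camera.

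Energy metabolism genes ranked higher, and this moved with the muscle transcripts of exercise 3, where muscle loci took 5.72% of gene counts. Glycolysis and hypoxia genes had 17 of 18 loci above 0 (median 0.55, camera adjusted p = 9.49e-04, adjusted p = 0.943 with an estimated correlation), and oxidative phosphorylation genes 19 of 24 (median 0.54, camera adjusted p = 0.0188, adjusted p = 0.943 with an estimated correlation). Pkm, a pyruvate kinase, stood at 702 FPKM in exercise 3, 161 and 175 FPKM in exercise 1 and 2, and 112, 128 and 224 FPKM in controls. Eno1 lay above all controls in every exercise library (log2 fold change 0.51 ± 0.21). Idh2 was at 158 FPKM in exercise 3 and 37.4 FPKM or less elsewhere. Without exercise 3 the glycolysis adjusted p was 0.467, and the oxidative phosphorylation list turned lower (adjusted p = 0.0511); the latter call also ended without control 1 (0.162) or control 2 (0.0730), with limma on log2(FPKM + 0.1) (0.0984) and on median-ratio scaled values (0.0767). Without both control 3 and exercise 3, the libraries with most muscle transcripts, the glycolysis list still ranked higher (camera adjusted p = 0.00804, adjusted p = 0.809 with an estimated correlation), and the oxidative phosphorylation list did not pass (0.566). The skeletal muscle list itself had a camera adjusted p of 0.161, which was 0.00519 with the replicate block, 0.0307 without control 3, 0.00432 without exercise 1, 0.00379 without exercise 2 and 0.00393 with these summed, and without exercise 3 (0.119) or control 1 (0.983) it turned lower. Without both control 3 and exercise 3 it was 0.644, and with an estimated correlation the list did not pass whichever single library was left out.

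Fat cell genes and inflammatory secretion genes ranked lower after exercise, and both moved with control 3, the library with fat and skin transcripts. Adipogenic genes had 3 of 19 loci above 0, a median of -0.53 and a camera adjusted p of 0.0277 (adjusted p = 0.943 with an estimated correlation). Fabp4, a fatty acid binding protein, was at 421 FPKM in control 3, 51.8 and 39.5 FPKM in control 1 and 2, and 25.2, 25.8 and 61.2 FPKM after exercise. Pparg, the regulator of fat cell differentiation, had a log2 fold change of -0.57 ± 0.42. Senescence and inflammatory genes had 3 of 12 loci above 0, a median of -0.41 and a camera adjusted p of 0.0277 (adjusted p = 0.943 with an estimated correlation). Serpinb2 (-1.56 ± 0.39) and the chemokine Ccl2 (-2.30 ± 0.87) lay below all controls in every exercise library, Cxcl1 had a log2 fold change of -2.89 ± 1.13, and Cdkn1a one of 0.01 ± 0.49. Without control 3 the adipogenic list turned higher (adjusted p = 0.0752) and the inflammatory list had an adjusted p of 0.728. The adipogenic call also ended without exercise 1 (0.252) or exercise 2 (0.255), and the inflammatory call without exercise 3 (0.455), all camera adjusted p-values. Both ended with limma on log2(FPKM + 0.1) (0.218 adipogenic, 0.108 inflammatory) and on median-ratio scaled values (0.0800 for both), and without both control 3 and exercise 3 (0.757 and 0.644). The adipogenic call also ended with no expression minimum (0.0723) and with exercise 1 and 2 summed (0.230).

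**Figure D2:**
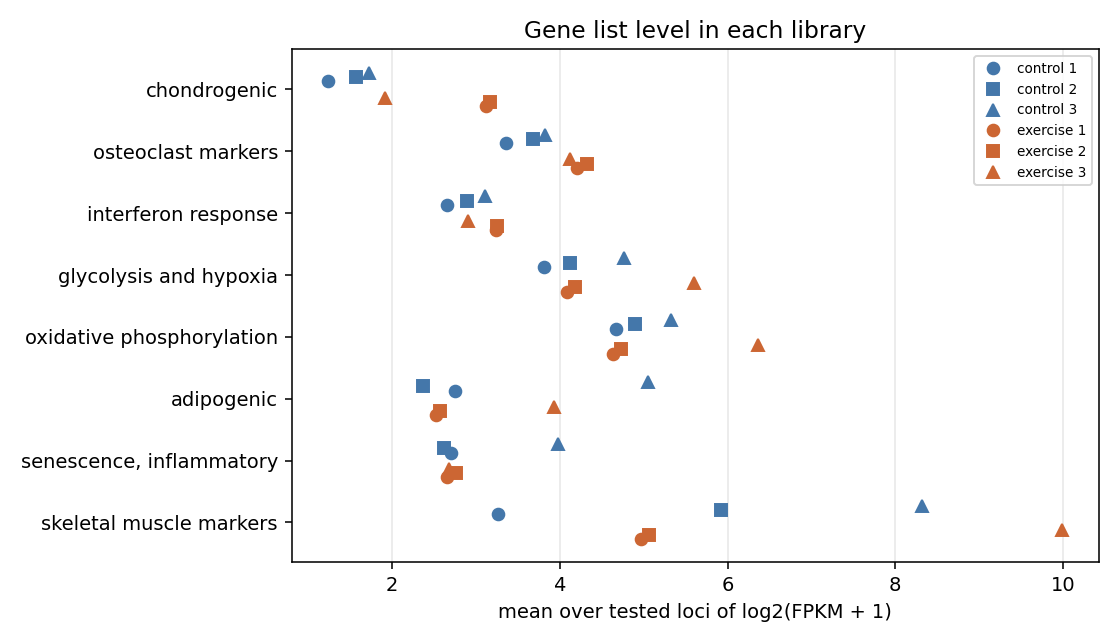
Mean of log2(FPKM + 1) over the tested loci of 8 gene lists, 1 point per library, blue for control and orange for exercise. The chondrogenic list stood at 3.12 and 3.17 in exercise 1 and 2 and at 1.92 in exercise 3, and the skeletal muscle list at 9.99 in exercise 3.

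In all, 7 of 25 lists passed camera with a preset correlation, 5 higher and 2 lower. With an estimated correlation 0 passed, and fry, which asks whether a list's genes move on balance in 1 direction, called 0. Of 377 members 0 passed in edgeR over all genes or adjusted over the list alone. Without control 3 the number of lists was 12. The osteogenic list had 11 of 18 loci above 0 (camera adjusted p = 0.0616): the bone phosphatase Alpl had a log2 fold change of 0.78 ± 0.23, Sp7 one of 0.78 ± 0.51 and Runx2, the bone master regulator, one of 0.33 ± 0.30. This list passed without control 3 (7.75e-08), exercise 3 (0.00255) or both (1.05e-10). It also passed with limma, a change of tool and input, on log2(FPKM + 0.1) (0.0453) and on quantile-normalized log2(FPKM + 1) (0.0432). It did not pass without control 1 (0.538), control 2 (0.950), exercise 1 (0.512) or exercise 2 (0.363), these being camera adjusted p-values with a preset correlation. With an estimated correlation the adjusted p was 0.943 with all libraries, 0.510 without control 3, 0.845 without exercise 3 and 0.340 without both. Spp1, osteopontin, passed as a gene without both (edgeR adjusted p = 0.0339), with exercise 1 and 2 counted as independent, and not with all libraries (0.992). It was highest in control 3, at 162 FPKM, and at 34.3 and 36.7 FPKM in control 1 and 2. In exercise 1, 2 and 3 it was at 136, 145 and 97.7 FPKM. Among Wnt genes (adjusted p = 0.534) the osteocyte inhibitor Sost had a log2 fold change of -1.48 ± 0.49, Sfrp1 one of -0.57 ± 0.24 and Ctnnb1 one of 0.47 ± 0.23. Stromal marker genes (adjusted p = 0.609), BMP and TGF-beta genes (0.534), load response genes (0.534), matrix genes (0.494) and antioxidant genes (0.943) did not pass by camera. Their named members included Kitlg (-0.98 ± 0.39), Nt5e (0.14 ± 0.37), Bmp2 (-0.57 ± 0.25), Piezo1 (0.17 ± 0.19), Tnc (0.72 ± 0.48) and Sod1 (-0.54 ± 0.18). Cell cycle genes (0.494), immediate early genes (0.836), osteoclast support genes (0.534) and markers of monocytes (0.447), neutrophils (0.455), lymphocytes (0.572), erythroid cells (0.482), megakaryocytes (0.819), endothelium (0.353) and smooth muscle (0.836) did not pass either, these numbers being camera adjusted p-values. Matrix genes ranked higher with a median log2 fold change of -0.09 and a mean of -0.12, BMP and TGF-beta genes lower with a median of 0.02, and megakaryocyte markers higher with a mean of -0.0029, so sign and test differed there. Several passed with a preset correlation once a library was left out, and with an estimated correlation 0 of 25 lists passed whichever single library was left out. Without control 3 matrix genes (8.42e-09), Wnt genes (0.0211), load response genes (0.0104) and immediate early genes (0.00447) ranked higher, and cell cycle genes (5.31e-05) lower. Their adjusted p-values with an estimated correlation were 0.657, 0.510, 0.657, 0.518 and 0.657. Without exercise 3 monocyte (4.05e-05), neutrophil (1.23e-04) and erythroid (0.00501) markers ranked higher and smooth muscle markers (0.0334) lower, and with an estimated correlation their adjusted p-values were 0.192, 0.845, 0.845 and 0.845. Without control 2 cell cycle genes (7.31e-05), erythroid markers (0.00541) and megakaryocyte markers (0.00572) ranked higher, and without control 1 cell cycle genes (0.0373) did, while immediate early genes (0.0490) ranked lower. With an estimated correlation the adjusted p-values were 0.867, 0.867 and 0.781 without control 2 and 0.953 for both lists without control 1. Mki67 had a log2 fold change of -0.21 ± 0.56, Fos one of -0.28 ± 0.69, the neutrophil protease Prtn3 one of 0.76 ± 0.25 and Pf4, a platelet chemokine, one of -0.56 ± 0.36.

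The second comparison concerned circRNAs, which form when a downstream splice site joins an upstream one. Of 1403 circRNAs tested, 0 passed an adjusted p of 0.05 in edgeR, 29 had an unadjusted p under 0.05, and DESeq2 called 1. That circRNA, circRNA9509, lies between genes on chromosome 15 at 55151603 to 55209058 and had 14, 12 and 5 junction reads in the controls and 0 in each exercise library, at least 4.61-fold lower against a floor of 3 reads per library. A circRNA of Pcnx1 (circRNA22262, chromosome 6, 105642908 to 105658762, 3 exons) had 0 reads in each control and 12, 13 and 7 after exercise, at least 3.20-fold higher. Neither passed in edgeR with the read minimum (adjusted p = 0.998). With every circRNA above 0 in at least 1 library tested, 11 passed in edgeR, 5 higher and 6 lower. They included circRNA9509 (adjusted p = 0.0274), and 6 of the 11 had reads in 1 library only. Without exercise 3 circRNA9848 passed (edgeR adjusted p = 0.0138), with 93, 62 and 53 reads in controls and 0 in exercise 1 and 2 but 41 in the library left out (adjusted p = 0.998 with all 6). One of the 11, circRNA26002, ends at the same position on chromosome 6 (132075882). It had 86 reads in exercise 1 and 0 in the other libraries, so reads at that end were not absent from exercise 1. When scaled within circRNAs, 8.55% of those tested did not overlap between groups, where chance gives 10% if the libraries are exchangeable. Of these, the others of smallest p wholly above the controls, none past adjustment, came from Cr1l (log2 fold change 1.73 ± 0.61), Susd1 (1.63 ± 0.58), Crot (2.33 ± 0.88) and an intergenic site on chromosome 8 (3.27 ± 1.04). Read numbers were low, with 5, 2 and 1 in controls and 18, 20 and 7 after exercise for Cr1l. The others of smallest p wholly below came from Pwwp2a (-1.25 ± 0.31), 2 hosts without a symbol (-2.55 ± 0.81 and -1.54 ± 0.52) and a site on chromosome 4 (-1.51 ± 0.45). Per gene count the same 8 stayed apart except that of Pwwp2a, which overlapped, with a log2 fold change of -0.58 with gene count totals as library sizes. The most abundant circRNA, of the host written Nf1x, had 787, 770 and 1234 reads in controls and 1765, 2130 and 1354 after exercise (log2 fold change 0.32 ± 0.42). Those of Ttc3 (0.64 ± 0.51), Spidr (0.56 ± 0.22) and intergenic sites on chromosome 2 (-0.63 ± 0.47) and 3 (0.04 ± 0.25) followed. Scaled within circRNAs, 48.5% of log2 fold changes were above 0; with gene count totals as library sizes, 82.2% were, with a median of 0.56.

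More circRNAs were detected in exercise 1 and 2 than in any control, and fewer in exercise 3. The numbers above 0 were 10993, 10278 and 9446 in controls and 16614, 17516 and 7694 after exercise, means of 10239 ± 774 and 13941 ± 5429 (SD, n = 3 each; exact permutation test, two-sided, p = 0.4, where 3 against 3 cannot go below 0.1). Without exercise 3 the difference was 6826 (exact permutation p = 0.1). At an equal 32887 junction reads the expected numbers were 9370, 9522 and 8991 in controls and 10614, 10654 and 7694 after exercise (exact p = 1). Junction reads per 1000000 gene counts were 644, 453 and 463 in controls and 943, 1054 and 355 after exercise (exact p = 0.4). Across 778 circRNAs with a tested host, the change of a circRNA and of its host gene had a Spearman correlation of 0.15, where circRNAs are not independent replicates. Without control 3 it was 0.28.

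**Figure D3:**
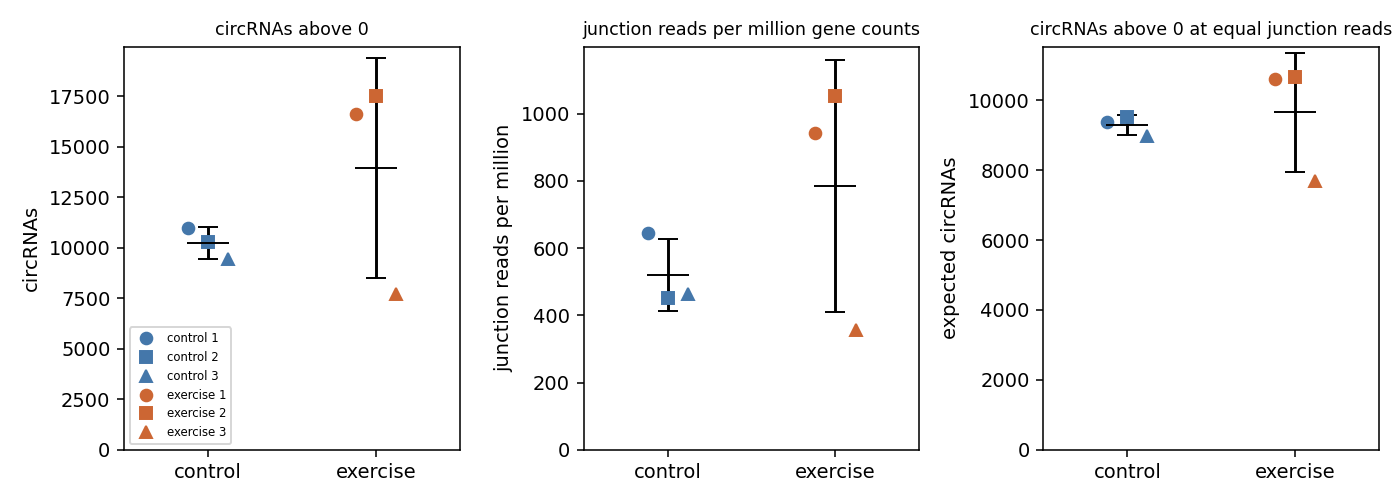
circRNAs above 0, junction reads per 1000000 gene counts, and expected circRNAs at 32887 junction reads, 1 point per library, with the mean (line) and SD (bars) of each group of 3. Exercise 1 and 2 lay above the controls and exercise 3 below them in each panel.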

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

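The alternatives without both control 3 and exercise 3, with exercise 1 and 2 summed, with sample weights, with gene count totals as circRNA library sizes, at equal junction reads, and with an estimated correlation without single libraries or without both control 3 and exercise 3, were chosen after seeing the data, and limma on log2(FPKM + 1) was added as the test planned for FPKM. The count of genes past adjusted p was 0 in edgeR; it was 18 with DESeq2, 16 without control 3 and exercise 3, 5 with limma voom sample weights, and 0 in the other alternatives, each single library left out included. The cause was not tested. circRNA calls were 11 with circRNAs above 0 in at least 1 library, 1 with DESeq2 and 0 to 1 without single libraries. List calls were 7 in the main edgeR fit. With limma on FPKM, which changes the tool and the input as well as the scaling, they were 4 on median-ratio scaled log2(FPKM + 1) (4 higher) and 8 on quantile-normalized log2(FPKM + 1). With limma on log2(FPKM + 0.1) they were 5 (5 higher, 0 lower, 4 of them among the 7). In edgeR they were 6 with no expression minimum, 6 with exercise 1 and 2 summed and 9 without control 3 and exercise 3 (4 among the 7). Without single libraries they were 6 to 12. With an estimated correlation they were 0 with all libraries, 0 without control 3 and exercise 3 and 0 without each single library. The replicate block gave 0 genes, 0 circRNAs and 8 lists, adding the skeletal muscle list, and changed no other call. The difference in detected circRNAs ranged from 1915 to 6826 without single libraries, and the host correlation from 0.16 to 0.28.

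Some lists turned direction. Without control 3 the adjusted p-values by camera were 0.0752 (adipogenic), 0.0211 (Wnt), 0.00447 (immediate early) and 5.31e-05 (cell cycle, lower). Without exercise 3 they were 0.0511 (oxidative phosphorylation) and 0.0334 (smooth muscle). Without both they were 0.757 (adipogenic), 0.00721 (cell cycle), 0.644 (senescence) and 0.566 (oxidative phosphorylation), and with an estimated correlation besides 0.890 (adipogenic and oxidative phosphorylation), 0.875 (cell cycle) and 0.876 (senescence). With an estimated correlation they were 0.730 (adipogenic) without control 3 and 0.845 (oxidative phosphorylation) without exercise 3. Over single libraries left out the adjusted p ranged from 4.83e-05 to 0.255 (adipogenic), 0.0211 to 0.792 (Wnt), 0.00447 to 0.918 (immediate early), 5.31e-05 to 0.990 (cell cycle), 1.00e-05 to 0.162 (oxidative phosphorylation) and 0.0334 to 0.950 (smooth muscle). Of 2776 values of named genes and circRNAs under alternatives, 100 had the other sign and 17 passed.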

Other observations

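The tests of ribosomal protein genes, of muscle loci above every control, of epidermis loci with no expression minimum, of sequencing depth, of exercise 1 against exercise 2 and of cartilage genes against control 1 and 2 alone were chosen only after the result was seen. Ribosomal protein genes, which encode the structural proteins of ribosomes, were taken as loci named Rpl or Rps followed by a digit. That pattern can also take in kinase genes named Rps6k, and it leaves out genes named Rplp. The loci so named lay low after exercise. Of 87 tested loci 81 had a log2 fold change below 0, with a median of -0.64, and 35 (40.2%) had every exercise library below every control (camera p = 2.20e-25 with a preset correlation, p = 0.119 with an estimated correlation). Their share of gene counts was 2.12% ± 0.625 in controls and 1.28% ± 0.270 after exercise (SD, n = 3 each; exact permutation test, two-sided, p = 0.1, the smallest possible). The median was -0.31 without control 3, -0.42 without exercise 3 and -0.07 without both, so it rested on those 2 libraries. Ribosomal protein genes have many near-identical copies. Lists chosen on these libraries are not independent evidence of their direction. Of epidermis loci 0 of 18 were above 0, of adipocyte loci 1 of 15 and of growth plate cartilage loci 13 of 13. Their camera adjusted p-values were 9.07e-09, 0.00102 and 1.36e-15, and 0.311, 0.405 and 0.136 with an estimated correlation. Of the cartilage loci Col11a2 alone passed when adjusted over the list alone (edgeR adjusted p = 0.0472). As the list was chosen on these same libraries, that pass is no independent evidence, and over all genes its edgeR adjusted p was 0.992.

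Gng11 and Prkar2b, both expressed in platelets, lay below all controls in every exercise library, which raised the hypothesis of fewer platelet transcripts after exercise. Other platelet genes, 18 in number, had a median log2 fold change of -0.18, and 7 were above 0. The camera p for a lower rank was 0.132 with a preset and 0.639 with an estimated correlation, which leaves the hypothesis open. The counts of genes, circRNAs and lists were compared with other splits of the 6 libraries, of which there are 10, too few for a share under 0.05. Genes and circRNAs past adjusted p numbered 0 in the real split and at most 0 in the others, so all 10 splits gave as many, a comparison that separates nothing. At an unadjusted p under 0.05 there were 398 genes and 29 circRNAs in the real split and up to 2198 and 83 in the others (edgeR). Lists numbered 7 in the real split and up to 20 in the others, and up to 13 among the 4 splits that part all 3 pairs; all 10 splits gave 7 or more. Splits that put control 3 and exercise 3 together called 17 to 20 lists, which points to the structure of the samples.

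The first pattern weighed is the muscle, skin and fat transcripts of control 3 and exercise 3. Muscle tissue in exercise 3 may be a source: 100% of 17 loci of a second muscle list were highest there, with Pvalb at 1117 FPKM and Eno3 at 1083 FPKM, and the labels name no sort or gate. Skin tissue in control 3 may be another: with no expression minimum, 94.7% of the 19 loci of a second epidermis list above 0 in any library were highest there. Tacstd2 was at 13.9 FPKM in control 3 and at 1.19 FPKM or less elsewhere. Jup was at 23.7 FPKM in control 3 but also at 17.4 FPKM in exercise 3, and Cdh1 was at 9.53 to 13.8 FPKM in all 6 libraries. The share of 90% among the 10 tested loci decides nothing, as only 2 of these passed the expression minimum without control 3. An effect of exercise on muscle transcripts stays open: 0 of 25 loci of 2 muscle lists (0%) had every exercise library above every control, but control 3 lay above exercise 1 and 2 in all 25, which fixed that outcome, and exercise 1, 2 and 3 lay above the control of the same number in 25, 2 and 25 loci.

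The second pattern is the cartilage genes higher in exercise 1 and exercise 2. That these are 1 library deposited 2 times is argued against by a chi-square of 16.2 per gene and 2.90 per circRNA, where resampling of reads gives 1. For gene counts, which are estimates, that value of 1 is approximate. Whether the 2 libraries come from the same RNA or animals was not tested. Cartilage tissue in those libraries predicted that both would lie above the other 4 for most loci of a second cartilage list, and only 25% of 12 loci did, which met the bound set beforehand against it. After the result was seen that bound was judged wrong, because 7 of the 12 loci were highest in control 3 or exercise 3. Against control 1 and 2 alone, 10 of 12 lay above. That comparison was chosen after the result, on libraries where the pattern was first seen. It cannot tell cartilage tissue from a change in expression, so it is no evidence for cartilage tissue, and the source stays open. An effect of exercise in every library also stays open, as exercise 3 exceeded the control mean by a median of 0.37 on the log2(FPKM + 1) scale, within the SD of 0.56 between controls.

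The third pattern is the yield of junction reads per 1000000 gene counts, highest in exercise 1 and exercise 2. Sequencing depth, as far as gene counts measure it, is argued against: control 2 and exercise 3 had gene counts within 10% of those of exercise 1, whose yield was 2.08 times the higher of these. The lower yield of exercise 1 and 2 was 1.46 times the highest of the other 4 libraries, 1.74 times outside structural RNA and haemoglobin loci and 1.46 times without the 100 circRNAs of most reads, so neither the share of those loci nor a few circRNAs accounts for it. An effect of exercise may contribute, but exercise 3 had the lowest yield, 355 junction reads per 1000000 gene counts, and library preparation was not tested.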
